A study of Mus musculus with 2 samples.

How the data were processed

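Total RNA from the fetal ear of the mouse was profiled on 2 Affymetrix arrays at E18.5. 1 array held wild-type BALB/c RNA and 1 held RNA of a BALB/c fetus or fetuses null for both Myf5 and Myod1. Per the labels, RNA was extracted with Trizol and biotin-labelled cRNA was made from 6 µg of total RNA. The labels do not say which part of the ear was taken, how it was dissected, or whether the RNA came from 1 embryo or from a pool.

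The deposited table gives log2 values, 1 per probe set and array, for 35557 probe sets. The base of the logarithm is not stated and was read from the range of the values, which ran from 0.81 to 13.27 in the wild type and from 0.75 to 13.26 in the double knockout; a natural or decimal logarithm would put the upper end beyond what a scanner records. The submitters' processing notes name MAS5, with no version. The probe sets are those of a whole-transcript mouse gene array, a design without the mismatch probes that MAS5 reads, so the exact way the authors made the deposited log2 values stays unsettled. A background correction, a normalization between arrays and a genome build are not given in the sources used here. The median was 5.65 in the wild type and 5.70 in the double knockout. The trimmed means of the linear signals, leaving out 2% at each end, were 140 and 138, a ratio of 1.01, so the values were used on their deposited scale. Across probe sets the arrays correlated with r = 0.98, and probe sets are not independent replicates.

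Gene names came from the platform's annotation, which can be old. It paired 21789 probe sets with 1 gene and 1621 with several, and 12147 had no gene listed there. Of the probe sets with 1 gene, 21698 had an Entrez identifier found in a RefSeq gene table of a mouse assembly, and 0 symbols needed updating. That table was used for names, synonyms and neighbouring genes, and no coordinates are given because the build behind the array is not named. For each of 19938 genes the probe set with the highest mean linear signal was kept; 999 genes had more than 1. A floor was set on each array at the 50th percentile over all probe sets, and values below it were raised to it. The difference was log2 of the double knockout minus log2 of the wild type for the 12458 genes above the floor on at least 1 array, of which 11626 were above it on both, 450 in the wild type alone and 382 in the double knockout alone. Where 1 side lay at the floor the fold is a bound and is written "at least", and a count of genes within 2-fold or a list median takes such genes at their bound. Genes were counted at 2-fold or more. With 1 array per group no test across samples and no p-value is possible, and the number of arrays limits the precision of every value.

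The samples' groups, the settings above, 37 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists held muscle genes (contractile, calcium handling and energy metabolism, myogenic regulators, neuromuscular junction, heart-type), inner ear genes (hair cells, supporting cells, tectorial and otolithic matrix, ion transport, melanocytes, otic patterning), middle and outer ear patterning genes, and neuronal genes (sensory ganglion neurons, neurotrophic factors, Schwann cells, brain). Other lists held cartilage, bone, osteoclast, tendon, immediate early, erythroid, adipocyte, epidermal, hair follicle, ciliated epithelium, cell cycle, macrophage, endothelial, smooth muscle, sex-linked, hypoxia, p53, heat shock and housekeeping genes and the chromosomal neighbours of Myf5 and Myod1. A list's median difference was taken over its members above the floor on at least 1 array, where at least 4 entered. It was set against 10000 random lists of the same size matched on mean signal in 10 bins, and stood apart at or below the 2.5th or at or above the 97.5th percentile. This describes the arrays at hand and is not a test across animals. 11 more lists were added after the values had been seen and are used only in the closing section.

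The rule named Myf5, Myod1, Myog and Myf6, the 12 largest differences in each direction among genes above the floor on both arrays, and the 8 largest bounds in each direction. For each list it named the 3 members of highest signal and the member with the largest difference of 2-fold or more in each direction. Unnamed and predicted transcripts could be left out. Members beyond this rule are said to have been chosen after their values were seen.

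The alternatives were 5 other scalings (equal medians of expressed probe sets, quantile normalization, removal of the trend with signal by loess, equal trimmed means without muscle genes, equal housekeeping medians), floors at the 25th and 75th percentile, no floor, a pseudocount of each array's median signal without a floor, the median over a gene's probe sets, and thresholds of 1.5-fold and 3-fold. Lists were set against 1000 random lists under each. The calculation was tested on simulated data for the double knockout against the wild type over 12311 genes, made from each probe set's mean over the arrays with noise of 0.138 per array on the log2 scale. This is the robust spread of the observed differences divided by the square root of 2. Of these, 200 genes drawn from those above the 75th percentile of signal were changed. At 2-fold or more it recovered 50 of 50 genes simulated at a log2 difference of -2, 49 of 50 at -1.5, 50 of 50 at 1.5 and 50 of 50 at 2, and it counted 0 of 12111 unchanged genes. Of 200 unchanged random lists, 11 (5.50%) stood apart. Such noise is small beside a 2-fold difference, so the count of 0 unchanged genes was all but fixed by that setting. It also cannot stand for the spread between animals of 1 genotype, which was not measured. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.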

Results

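Gene expression was measured in the ear of mouse fetuses at E18.5, shortly before birth, on 1 array of wild-type tissue and 1 array of tissue null for Myf5 and Myod1. These genes encode the transcription factors that commit cells to skeletal muscle, and fetuses without both form little or no skeletal muscle. Each array gave a log2 signal for 35557 probe sets, with medians of 5.65 in the wild type and 5.70 in the double knockout. Of 19938 named genes, 12076 lay above the array's median in the wild type and 12008 in the double knockout. There was 1 array per genotype, so no difference below has a replicate check.

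The comparison asked how the ear's transcripts differ in a fetus null for both genes. Of the targeted genes, Myod1 (probe set 10553256) read 6.95 in the wild type and 6.38 in the double knockout, 1.49-fold lower. Myf5 (probe set 10372226) read 5.94 in the wild type, just above the floor, and 5.25, below the floor, in the double knockout. Each has 1 probe set, and whether it lies in the deleted part of the gene is not given in the sources used here, so these values say little about the labels. The related muscle regulators were further apart. Myf6 (probe set 10372230) read 8.04 and 4.27, at least 5.05-fold lower in the double knockout, and Myog (probe set 10349993) read 7.03 and 4.52, at least 2.51-fold lower. Myf6 is a chromosomal neighbour of Myf5, so an effect of the targeted allele on it cannot be told from a loss of muscle.

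Genes of the skeletal muscle contractile apparatus were far lower in the double knockout, by a median log2 difference of -3.67 with low values raised to the floor, or at least 12.7-fold. Adipocyte genes were higher there as a list, by a median of 0.51. So were brain genes, by 0.36, though this list did not stand apart with the floor at the 75th percentile. The single genes furthest in this direction were Bpifa2, the parotid secretory protein, at least 113-fold higher, and Smgc, a submandibular gland protein, at least 42.2-fold higher. The lists of inner ear genes for supporting cells, extracellular matrix, ion transport and patterning had medians from -0.02 to 0.01. Over all genes, 213 were at least 2-fold lower in the double knockout, 60 were at least 2-fold higher and 12185 were within 2-fold. Within 2-fold here means after raising low values to the floor, so for a gene at the floor on 1 array it does not exclude a larger difference. The lower genes comprised 115 above the floor on both arrays and 98 at the floor in the double knockout, and the higher genes comprised 42 above it on both and 18 at the floor in the wild type. Of the 213 lower genes, 79 belonged to a muscle list, and of the 60 higher genes 0 did. At 16-fold or more, 29 genes were lower, of which 27 belonged to a muscle list. The other 2, named after their values were seen, were Atp1b4, which encodes a muscle-enriched relative of the Na,K-ATPase beta subunits, and Apobec2.

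**Figure D1:**
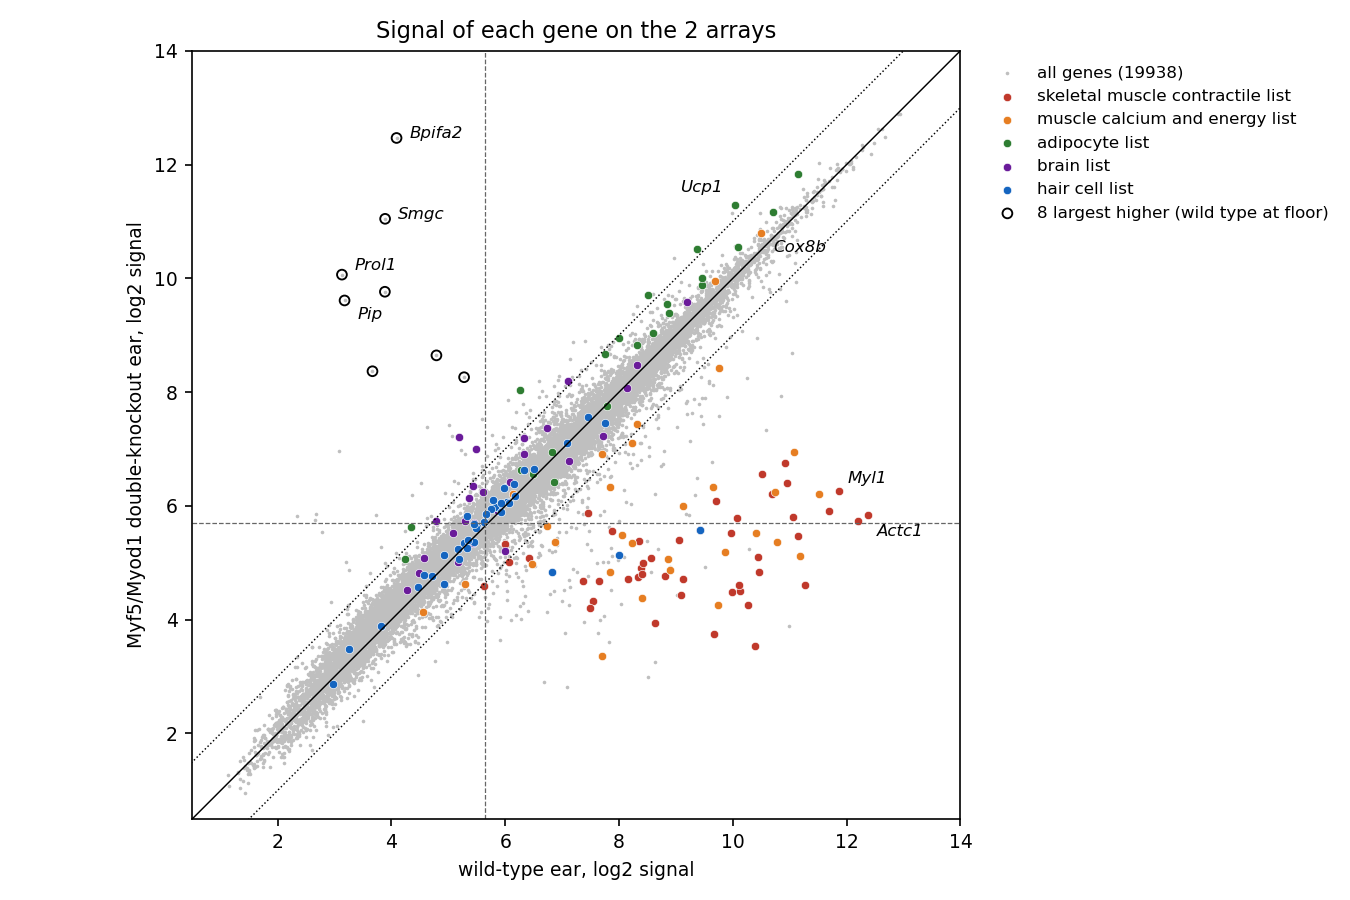
Each point is a gene, with its log2 signal in wild-type ear on the x axis and in double-knockout ear on the y axis; the solid line marks equal signal, dotted lines 2-fold differences and dashed lines the floor of each array. Members of the contractile list (red) lie below the diagonal, with Actc1 at 12.38 and 5.84, and the 8 genes with the largest higher bounds (open circles) lie at the upper left, with Bpifa2 at 4.09 and 12.47.

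For scale, the log2 differences of the 11626 genes above the floor on both arrays had a standard deviation of 0.344, and of 0.291 without the muscle lists, with a 1st percentile of -0.874 and a 99th of 0.754. Probe sets of the same gene differed with a standard deviation of 0.168 over 619 genes, which covers probe noise and not the spread between animals. Of 15 genes past 2-fold with several probe sets above the floor, 14 had all of them in the same direction, and the exception, named after its values were seen, was Tmod1, with probe sets at -1.64 and 0.34. The counts depend on the floor: with it at the 75th percentile, 111 genes were lower and 21 higher.

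Within the contractile list, 41 of the 44 genes above the floor were at least 2-fold lower, 0 were higher and 3 were within 2-fold, and the median lay below those of all 10000 random lists. With the floor at the 75th percentile the median was -2.49. The largest differences measured on both arrays were those of the sarcomeric actins Actc1 (12.38 in the wild type, 5.84 in the double knockout, 93.2-fold lower) and Acta1 (88.3-fold lower). The fast troponins Tnnt3 and Tnni2 were 55.2-fold and 38.1-fold lower, the myosin light chains Myl1 and Myl4 48.5-fold and 23.4-fold lower, and Tpm2, a tropomyosin, 18.0-fold lower. Des, the intermediate filament protein of muscle, was 22.4-fold lower, and Pdlim3, a protein of the Z-disc, 19.6-fold lower. Several genes were at the floor in the double knockout and have only a bound. Myh8, the perinatal myosin heavy chain, was at least 47.2-fold lower, Actn2 at least 43.8-fold, Tnnc2 at least 27.1-fold and Neb, which encodes nebulin, at least 26.7-fold. The other 3 members, Tcap, Klhl40 and Trim63, named after their values were seen, were at the floor in the double knockout, with wild-type signals of 6.42 or less. Their bounds were at least 1.65-fold, 1.29-fold and 1.22-fold lower.

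Genes of muscle calcium handling and energy metabolism were lower by a median of -2.45, with 22 of 28 at least 2-fold lower, 0 higher and 6 within 2-fold. This median also lay below all random lists, and was -1.43 with the floor at the 75th percentile. Atp2a1, the calcium pump of the sarcoplasmic reticulum, was at least 44.8-fold lower, its calcium-binding partner Casq1 at least 33.7-fold and Trdn at least 26.2-fold. The 14 probe sets of Trdn above the floor ranged from -4.71 to -0.85. Ckm, the muscle creatine kinase, was 39.5-fold lower, the glycogen phosphorylase Pygm 22.5-fold and the enolase Eno3 17.4-fold. Cox8b, a cytochrome oxidase subunit of muscle that brown fat also makes, did not share this direction, with 10.49 in the wild type and 10.80 in the double knockout.

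Myogenic regulators had a median of -0.85. All 16 members were below 0, with 7 at least 2-fold lower and 9 within 2-fold. Mymk, the membrane protein that drives fusion of myoblasts, was at least 6.93-fold lower and Mef2c 2.06-fold lower, whereas Mef2a and Mef2d differed by -0.16 and -0.44. Genes of the muscle side of the neuromuscular junction had a median of -0.75, with 6 of 12 at least 2-fold lower, 0 higher and 6 within 2-fold. The acetylcholine receptor subunit Chrna1 was at least 3.89-fold lower and Ache 2.21-fold lower, while Prkar1a differed by -0.36 and Lrp4 by 0.01. Both medians lay below all random lists. Of 7 genes usual in heart muscle, 3 were at least 2-fold lower and 4 within 2-fold: Tnnt2 was 9.96-fold lower, Myl3 at least 2.68-fold and Myl2 at least 2.67-fold. Their median of -0.16, at the 3.99th percentile, did not stand apart.

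Hair cells are the mechanosensory cells of the inner ear. Of the 22 hair cell genes above the floor, 19 were within 2-fold, 3 were at least 2-fold lower and 0 were higher, and the median of 0.09, at the 91.5th percentile, did not stand apart. The largest difference was that of Smpx, at least 13.3-fold lower, a gene that the contractile list also holds. The other 2, named after their values were seen, were Mlf1 (8.0 in the wild type, 5.13 in the double knockout) and Chrna9 (6.81 and 4.84). Whole-tissue RNA does not tell whether the signals lost in these 3 genes came from hair cells. Anxa4 differed by -0.30 and Rprm by 0.11. Atoh1, the transcription factor that specifies hair cells, read 6.17 on both arrays, and Myo7a, a hair cell myosin, read 6.03 and 6.07; these were also named after their values were seen. Most members lay near the floor. With the floor at the 75th percentile the 4 members left were Smpx, Mlf1, Anxa4 and Rprm, and their median was -0.47, at the 0.1st percentile. That value rests on these few genes, Smpx of the contractile list among them, and does not speak for the hair cell list as a whole.

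Genes of supporting cells and Notch signalling had a median of 0.01 at the 72.6th percentile, with 23 of 24 within 2-fold. S100a1 differed by 0.13, Notch1 by 0.03 and Bmp4 by -0.13, and Fabp3, which the muscle energy list also holds, was 2.18-fold lower. All 13 genes of the tectorial membrane and the otolithic and cupular matrix were within 2-fold, with a median of -0.01 at the 47.5th percentile. Oc90, the main protein of otoconia, read 11.28 in the wild type and 11.26 in the double knockout, and Tecta, of the tectorial membrane, 8.74 and 8.76. Sparcl1 differed by -0.12. All 15 genes of ion transport and endolymph were within 2-fold, with a median of 0.00 at the 50.5th percentile; Pou3f4 differed by 0.31, Ednrb by 0.03 and Cldn11 by 0.26. The 6 melanocyte genes had a median of 0.01 at the 54.5th percentile, with Sox10 at -0.05, Kit at 0.24 and Dct at 0.33. The 21 otic patterning genes were all within 2-fold, with a median of -0.02 at the 35.6th percentile, and Lmo4, Eya1 and Tbx18 differed by 0.19, 0.04 and 0.23. Of 21 genes that pattern the middle and outer ear, 20 were within 2-fold and Tbx15 was 2.12-fold lower; Prrx1 differed by -0.17. Their median was -0.06, at the 8.36th percentile. None of these 6 lists stood apart.

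Neuronal lists went different ways. The sensory ganglion list had a median of 0.15, at the 99.99th percentile, with 24 of 25 within 2-fold and Neurod1 2.24-fold higher in the double knockout. Its members of highest signal were Stmn2, Nefl and Ina, with differences of 0.21, -0.17 and 0.51. Members went both ways: Elavl3 and Mapt, which neurons in general express, differed by 0.72 and 0.66, and Isl1 and Prph, typical of peripheral neurons, by -0.44 and -0.52. These 4 were named after their values were seen. Brain genes were higher by a median of 0.36, above all random lists, with 3 of 20 at least 2-fold higher and 17 within 2-fold. Those 3 were cortical transcription factors: Neurod6, at least 2.96-fold higher, and, named after their values were seen, Tbr1 and Neurod2. Zic2, Pcp4 and Zic1 differed by 0.39, 0.16 and -0.06. With the floor at the 75th percentile the brain list had 6 members and a median of 0.08 at the 90.4th percentile, and did not stand apart. Among the 12 largest higher differences measured on both arrays, which were picked by size and not as a group, Fezf2, a transcription factor of deep-layer cortical neurons, read 6.05 and 7.85, 3.49-fold higher in the double knockout. Lhx2 was 3.02-fold higher, Cntn2 2.73-fold, Grm5 2.58-fold and Dab1, the adaptor of reelin signalling, 2.5-fold. Mpped1 was 3.26-fold higher, Igfbpl1 2.78-fold, and the nuclear receptors Nr4a2 and Nr4a3 2.81-fold and 2.80-fold.

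Schwann cell and myelin genes had a lower median, -0.26 at the 0.01st percentile, with all 14 within 2-fold. Pmp22 differed by -0.24 and Ngfr by -0.53, and Fabp7 by 0.51 in the other direction. The 6 neurotrophic factors and receptors had a median of -0.13 at the 10.7th percentile and did not stand apart, with Gfra2 at -0.21 and Gfra1 at 0.18.

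Skeletal lists were close to 0. Cartilage genes had a median of 0.04 at the 83.2nd percentile, with 22 of 23 within 2-fold; Col2a1, Cnmd and Acan differed by 0.05, 0.21 and 0.04, and Col10a1, the collagen of hypertrophic cartilage, was 2.14-fold lower. All 16 bone genes were within 2-fold, with a median of 0.02 at the 63.6th percentile, and Sparc, Col1a1 and Col1a2 each differed by -0.10. The 13 osteoclast genes had a median of -0.01 at the 47.6th percentile, with Ctsk at -0.01, Mmp14 at -0.22 and Mmp9 at 0.15. Tendon and fibrous connective tissue genes, by contrast, had a median of -0.30, below all random lists, with 18 of 20 below 0, 3 at least 2-fold lower and 17 within 2-fold. Thbs4, a matrix protein of tendon and muscle attachments, read 9.37 in the wild type and 6.48 in the double knockout, 7.39-fold lower. The other 2, named after their values were seen, were Kera, at -1.32, and Tnmd, the tenomodulin gene, at -1.18. The abundant members Bgn, Dcn and Postn differed by -0.10, -0.14 and -0.49.

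Immediate early genes, which respond to tissue handling as well as to mechanical load and other stimuli, were lower as a list, with a median of -0.35 and all 17 members below 0. None passed 2-fold after flooring, but Ankrd1, Fosb, Atf3 and Ier3, named after their values were seen, were at the floor in the double knockout and have only bounds. Ankrd1 read 6.40 and 4.16, at least 1.62-fold lower. Jun differed by -0.44, Myc by -0.22 and Ccn2 by -0.15. Outside the list, Nr4a2 and Nr4a3, relatives of its member Nr4a1, went the other way and were 2.81-fold and 2.80-fold higher. Smooth muscle genes had a median of -0.39, with 11 of 12 within 2-fold and Acta2 2.02-fold lower; Myl9 differed by -0.58 and Smtn by -0.08. Macrophage and granulocyte genes had a median of -0.31, with all 16 members below 0 and 15 within 2-fold. The neutrophil gene Ngp was at least 2.90-fold lower, and Csf1r, C1qb and Mrc1 differed by -0.29, -0.32 and -0.28. These 3 medians lay below all random lists. Endothelial genes did not stand apart, with a median of -0.02 at the 46.3rd percentile over 15 genes within 2-fold, and Emcn, Cdh5 and Eng at 0.21, -0.02 and 0.06. The 5 erythroid genes had a median of -0.02 at the 41.6th percentile, with Alas2, Slc4a1 and Fech at 0.15, -0.28 and -0.02.

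The largest differences towards the double knockout were in genes at the floor in the wild type. Bpifa2 read 4.09 in the wild type and 12.47 in the double knockout, at least 113-fold higher. Smgc read 3.89 and 11.05, at least 42.2-fold higher, and Prol1, a secreted proline-rich protein, was at least 21.4-fold higher. A2ml1, a protease inhibitor, was at least 17.4-fold higher, and Pip, the prolactin-induced protein of salivary and lacrimal glands, at least 15.6-fold. Lpo, the lactoperoxidase of saliva and tears, was at least 8.0-fold higher, the salivary carbonic anhydrase Car6 at least 6.60-fold and the salivary mucin Muc19 at least 6.13-fold. Another probe set of Muc19 above the floor differed by 0.68. Wfdc18, another secreted protein, was measured on both arrays and was 2.74-fold higher.

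Adipocyte genes were higher in the double knockout by a median of 0.51, above all random lists. Of 20 members 18 were above 0, 4 were at least 2-fold higher and 16 were within 2-fold. Retn, which encodes the fat cell hormone resistin, was 3.45-fold higher, and Ucp1, the uncoupling protein of brown fat, read 10.03 and 11.29, 2.40-fold higher. The other 2, named after their values were seen, were Cidea and Agpat2, at 1.20 and 1.14. Gpd1 and Fabp4 differed by 0.68 and 0.47, and Thrsp, a regulator of lipid synthesis outside the list, was 2.64-fold higher.

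Among epithelial lists, epidermal genes had a median of 0.02 at the 65.9th percentile, with 11 of 13 within 2-fold. The keratins of differentiated epidermis were the exceptions, Krt1 at least 3.67-fold higher and Krt10, named after its values were seen, at 5.01 in the wild type and 7.42 in the double knockout. Krt5, Perp and Krt15 differed by 0.05, 0.05 and 0.18. Of the hair follicle list 3 genes lay above the floor, too few for a median, with Lef1, Msx2 and Krt34 at 0.25, 0.22 and 0.05. The ciliated and secretory epithelium list had a median of -0.21 at the 0.7th percentile, with 7 of 8 within 2-fold and Tppp3 2.76-fold lower; Bpifa1 and Cyp2f2 differed by -0.21 and 0.62. This median was 0.03 with the floor at the 75th percentile, so its direction rests on the floor.

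**Figure D2:**
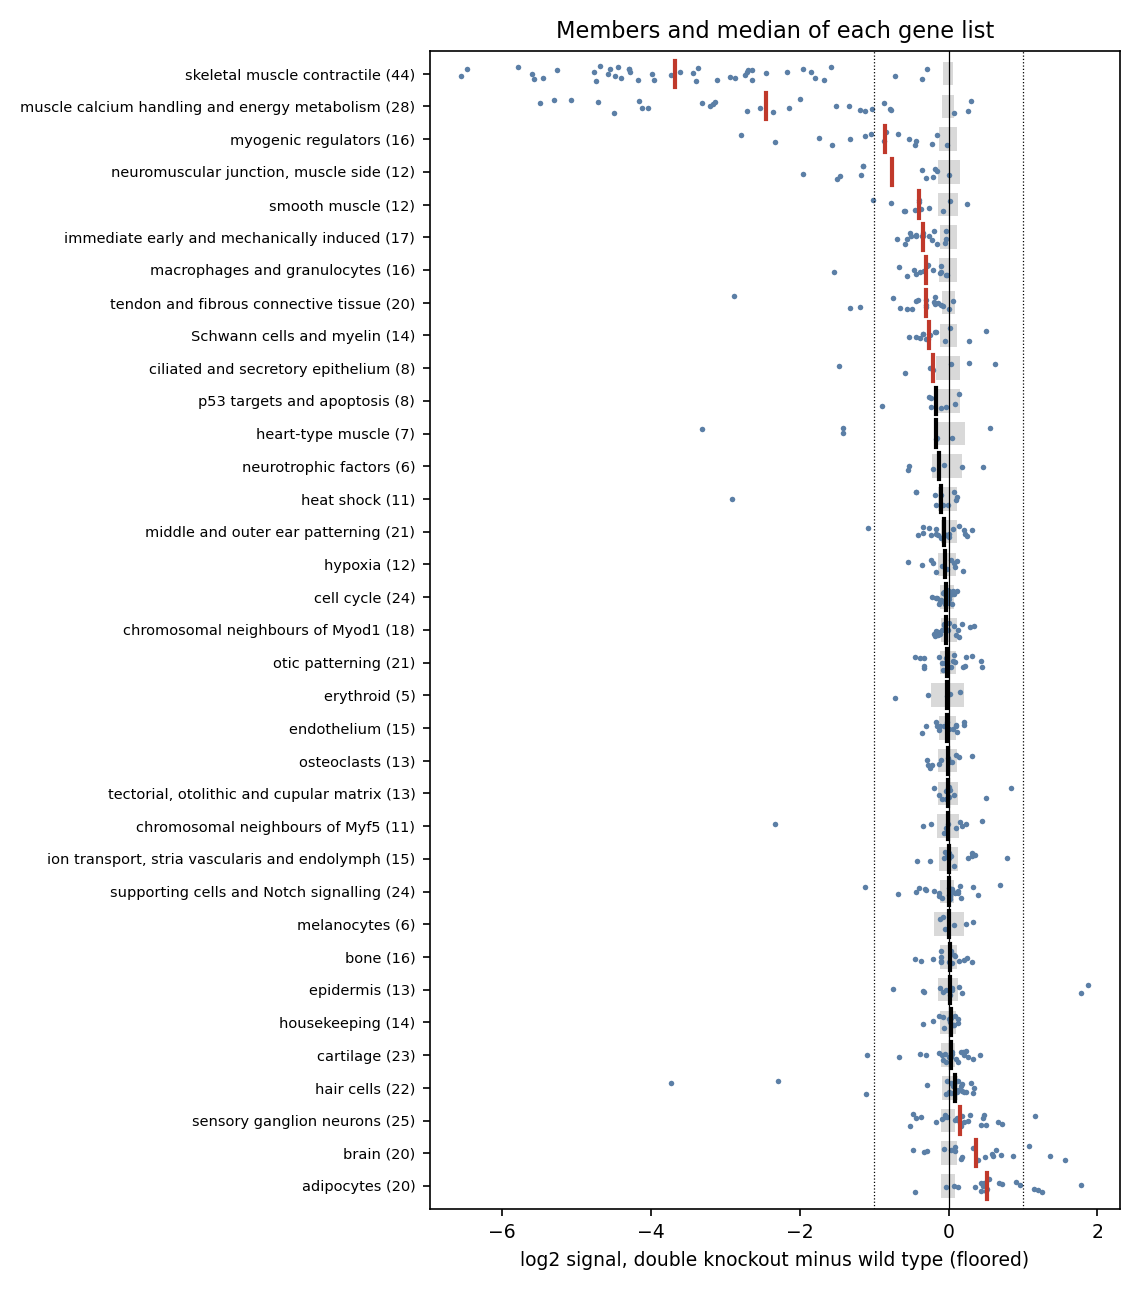
Each point is a gene and each row a gene list, with the number of members above the floor in parentheses; the x axis is the log2 signal of the double knockout minus that of the wild type after flooring. Vertical bars mark list medians, red where the list stood apart, grey boxes the range holding the middle 95% of random lists, and dotted lines 2-fold differences. The contractile list has the lowest median, -3.67, and the adipocyte list the highest, 0.51.

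Background lists gave the following values. Housekeeping genes had a median of 0.03 at the 72.1st percentile over 14 genes, with Eef1a1, Actb and Ppia at 0.00, 0.08 and 0.06. The 24 cell cycle genes had a median of -0.03 at the 35.5th percentile, with Pcna, Cdk1 and Ccna2 at -0.15, -0.07 and -0.02. The 12 hypoxia genes had a median of -0.05 at the 25th percentile, with Ldha, Pgk1 and Slc2a1 at -0.09, -0.20 and 0.11. The 8 p53 targets had a median of -0.17 at the 3.07th percentile, with Ccng1, Trp53inp1 and Phlda3 at -0.90, 0.09 and -0.26. The 11 heat shock genes had a median of -0.11 at the 6.11th percentile; Hspb1, a small heat shock protein abundant in muscle, was 7.5-fold lower, while Hspa8, Hspa5 and Hsp90aa1 differed by -0.01, -0.10 and -0.08. Chromosomal neighbours of Myf5 had a median of -0.01 at the 49.9th percentile over 11 genes, with Myf6 alone past 2-fold and Syt1, Nav3 and Ppp1r12a at 0.15, 0.10 and -0.06. Those of Myod1 had a median of -0.03 at the 23.9th percentile over 18 genes, with Ldha, Emp3 and Rps13 at -0.09, -0.18 and 0.00. Of the sex-linked list 3 genes lay above the floor, too few for a median. Xist read 10.68 in the wild type and 10.28 in the double knockout, and the Y-linked Eif2s3y and Uty read 2.67 and 2.35 in the wild type against 5.85 and 5.83, just above the floor, in the double knockout. Both were below the floor in the wild type, which leaves bounds of only at least 1.15-fold and 1.14-fold higher. Without the floor they were higher by 3.18 and 3.48, so the sex make-up of the samples may differ.

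In all, 13 of the 35 lists with a median stood apart, 10 lower and 3 higher in the double knockout. Independent lists of unrelated genes would give 1.75. Members of a real list can move together and some lists share members, so 1.75 is not the number to expect between any pair of tissue samples. Genotype cannot be separated here from anything else that differed between the tissue samples.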

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

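Probe sets without a gene name of their own entered no comparison, and some differed as much as named genes did. Of 13768 such probe sets, 4820 lay above the floor on at least 1 array. In the double knockout 15 of these were at least 2-fold higher, 9 with no gene listed and 6 with several genes, and 21 were at least 2-fold lower, 14 with no gene listed and 7 with several. Their log2 differences reached -4.54 and 1.44. These were counted after the comparison of named genes had been made, and no explanation was tested. With 1 array per genotype, no sample could be examined as an outlier within its group.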

How the results depend on the processing

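The alternatives were planned, whereas asking whether lists still stood apart under them was decided after the values were seen. No list that stood apart turned its direction under the 5 other scalings, which shifted the median of all genes by -0.01 to 0.08. Of the values of single named genes, 1454 moved by less than 1.5-fold and 102 by more, and none of those past 2-fold reversed. With the floor at the 75th percentile, 111 genes were lower and 21 higher, and the medians were -2.49 for the contractile list and -1.43 for calcium handling and energy metabolism. With a pseudocount, 34 genes were higher, and these medians were -2.96 and -1.86; both settings pull low values together by construction. Without a floor 92 genes were higher. A threshold of 1.5-fold gave 451 lower and 280 higher genes, and 3-fold gave 120 and 16. The ciliated epithelium list turned from -0.21 to 0.03 with the floor at the 75th percentile and to 0.04 with a pseudocount, and the cause was not tested.

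Of the 13 lists that stood apart, 11 did so under every alternative; the ciliated list was lost under all 4 other treatments of low signals, and the brain list with the floor at the 75th percentile. That floor brought hair cells (-0.47), ion transport (0.17) and neurotrophic factors (-0.37) past the limits. The hair cell value rests on Smpx, Mlf1, Anxa4 and Rprm alone, of which Smpx is also in the contractile list. Heart-type genes passed with the floor at the 25th percentile, without a floor and with a pseudocount, and erythroid and epidermal genes with a pseudocount. Leaving out probe sets by the ending of their identifiers was not run, since 0 have such endings, and no array could be left out. Signals near the array median limit most of what can be said of hair cell genes.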

Other observations

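The gene lists in this part were made after the comparison had been seen. The tests of salivary gland tissue, cerebral cortex tissue, neurons of every kind and lost muscle RNA were chosen after some or all of their values had been seen; those of epithelium and of fat cells were chosen before their own values were. Genes of fatty acid and triglyceride synthesis were higher in the double knockout. Their 22 members, 3 of them in another list, had a median log2 difference of 0.59, above all random lists, with 4 at least 2-fold higher, 0 lower and 18 within 2-fold. Fasn, the fatty acid synthase, read 9.98 in the wild type and 11.15 in the double knockout, 2.24-fold higher, and Acaca and Acly, which supply its substrate, differed by 0.80 and 0.80. Noradrenergic neuron genes, 7 of the 16 in another list, went the other way, with a median of -0.56 below all random lists. Of the 16, 4 were at least 2-fold lower. Th, the first enzyme of catecholamine synthesis, differed by -1.25, Dbh by -1.56 and the noradrenaline transporter Slc6a2 by -1.06. Some of these values had been seen when the list was made, and with the floor at the 75th percentile its median was -0.03 and it did not stand apart. Genes of sensory ganglia alone had a median of -0.29, at the 0.01st percentile, with all 17 within 2-fold. With that floor the median was -0.14 at the 3.7th percentile and did not stand apart either. Of the 17, 12 are in another list, so the neuron lists made here are not separate results. The sensory ganglion list fixed earlier went the other way, with a median of 0.15.

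Imprinted genes, which are expressed from 1 parental copy and include many regulators of fetal growth, had a median of -0.29, below all random lists. Of 24 members 20 were below 0, 5 were at least 2-fold lower and 19 within 2-fold. Zdbf2 differed by -1.65, Peg10 by -1.33 and Slc38a4 by -1.11, and Rtl1, at the floor in the double knockout, was lower by at least 2.60-fold. The abundant Igf2 and Dlk1 differed by -0.25 and -0.41. Some of these values too had been seen when the list was made, and which cells of the tissue gave these signals was not examined. Gh, the growth hormone gene, read 9.34 in the wild type and 6.20 in the double knockout, 8.85-fold lower, while the 6 anterior pituitary genes above the floor had a median of -0.03 at the 30.6th percentile. Lipf, a gastric lipase, read 8.50 and 2.98, at least 6.97-fold lower. Xist, made from the inactive X, was high on both arrays, at 10.68 in the wild type and 10.28 in the double knockout. The Y-linked Eif2s3y and Uty read 2.67 and 2.35 in the wild type, below its 25th percentile of 3.99. In the double knockout they were just above the floor, at 5.85 and 5.83, so they were higher by 3.18 and 3.48 without the floor. These values go with female RNA on both arrays and some male RNA in the double knockout alone, though the Y-linked signals were low. Sex was not separated from genotype in any pattern here.

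The 8 genes with the largest higher bounds, Bpifa2 and Smgc among them, were higher in the double knockout by at least 6.13-fold to at least 113-fold, the lowest being Muc19, whose other probe set above the floor differed by 0.68. They were picked by size, and no list of salivary secretory genes was fixed beforehand. A higher share of epithelium of every kind is argued against as the whole source, since it would move epithelial genes together by about as much, and 22 simple epithelium genes, of which 0 are in another list, had a median of 0.22 (95% bootstrap interval over genes 0.15 to 0.35), though above all random lists. Salivary gland tissue in the double-knockout sample stays open. The 12 salivary acinar and duct genes above the floor, 2 of them in a list fixed earlier, had a median of 0.25. This was only 0.026 (-0.22 to 0.42) above that of simple epithelium, so they do not separate it from epithelium in general. Of these 12, 10 lay above the floor in the wild type too, where the 8 genes did not. They are thus made there without the secretory genes, and their median cannot tell whether gland tissue was added. Ehf differed by 0.80 and the abundant Creb3l1 by 0.06. The dissection is not described, and a difference between the genotypes themselves was not tested.

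Brain genes were higher in the double knockout, by a median of 0.36. With the floor at the 75th percentile the brain median was 0.08, and the list did not stand apart. Whether neurons of every kind had a higher share cannot be decided here. The 25 peripheral neuron genes, 19 of them in another list, had a median of -0.32 (95% bootstrap interval -0.55 to -0.09). The 16 of them in no list fixed earlier had one of -0.30, at the 0.01st percentile. The peripheral neuron list was made after values had been seen, so its direction may follow from the choice of members. The sensory ganglion list fixed earlier, which also holds genes of neurons in general, went the other way at 0.15. Cerebral cortex tissue in the double-knockout sample stays open: 21 cortex genes, 18 of them above the floor in the wild type and 5 in a list fixed earlier, had a median of 0.33 and 14 hindbrain genes, 5 of them in such a list, one of 0.00, a difference of 0.33 whose interval, -0.03 to 0.56, includes 0; with the floor at the 75th percentile the cortex list had a median of 0.12, at the 96.1st percentile, and did not stand apart. Nfix, an abundant member of the cortex list, differed by 0.34. Dissection and genotype cannot be told apart with 1 sample each.

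Adipocyte genes were higher in the double knockout by a median of 0.51. That median lay 0.513 (95% bootstrap interval over genes 0.44 to 0.82) above that of the 12331 other genes outside the muscle lists. This follows from the list standing above all random lists and is no separate test. Loss of muscle RNA, which would raise the share of all other transcripts alike, is argued against as the whole source. Macrophage and endothelial genes did not rise with the adipocyte genes, with medians of -0.31 and -0.02. Brain genes did, at 0.36, but not apart from random lists with the floor at the 75th percentile. A rise common to all transcripts is not excluded as a part, since arrays on a similar scale would not show it. More fat cells in the double-knockout sample may account for the higher adipocyte genes. A list of 19 further adipocyte genes, all 19 also above the floor in the wild type, had a median of 0.27 (0.11 to 0.39), above all random lists. Its abundant members Nnat and Cd36 differed by 0.23 and 0.27, and whether their signal came from fat cells is not known. More transcript per fat cell would give the same list medians. Whether such a difference came with the dissection, the sex of the fetuses or the genotype was not tested.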
